A study of Mus musculus with 16 samples.

How the data were processed

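Tail DNA of 1 family of C57BL/6 mice was measured by array comparative genomic hybridisation, in which the DNA of an animal and that of a reference are labelled with different dyes and compete for the same probes. The family comprised 1 sire, 1 dam and 6 offspring, and the reference was 1 male mouse of the same colony. Each animal was hybridised on 2 arrays with the dyes exchanged, giving 16 arrays. The 2 arrays of an animal share the same DNA, so their mean counted as 1 replicate, and no measurement of a single animal has a biological replicate. Per the file headers, the 16 arrays lay on 2 slides: slide 1 carried the sire, the dam and offspring 1 and 2, and slide 2 carried offspring 3 to 6.

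The deposited scanner files were written by Feature Extraction 10.7.1.1 on a design annotated to mouse build mm9 (NCBI 37), per the file headers. The processed signals are an intensity per channel that the software had background-subtracted with spatial detrending and normalised between dyes by a linear factor; per the file headers no lowess step was applied. The raw median and background signals are also deposited as intensity, without normalisation. The deposited log10 ratio of red over green follows from the processed signals and was only compared with them. The deposited flags (other values, 0 or 1) mark outlier, saturated and dim spots. The deposited series value table holds log2 ratios whose scale and direction are not given in the sources used here: against the scanner values each column had a slope of 1 with the animal in Cy3 and of -1 with the animal in Cy5, so that it equals log2 of reference over animal on every array, with column medians between -0.01 and 0.03, and what centring was applied to some columns stays unknown. Other array platforms and the first screening array of the study were not used here.

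Each array held 44342 non-control spots and 3924 control spots, which were left out. A spot was left out of an array if it was an outlier in either channel (90 to 189 spots per array). A spot well above background in neither channel was left out too (622 to 2083 spots). No spot was saturated. Between 93.8% and 98.2% of spots were well above background in both channels, and the median signal over background was 17.1 to 30.5 in green and 16 to 34.2 in red. The number of arrays limits the precision. The log2 ratio of animal over reference was taken from the processed signals, centred on the median of each array, averaged over the spots of 1 probe and then over the 2 dye orientations. The array held 40325 distinct probes of 45 to 60 bases. Tiled regions were runs of at least 5 probes on 1 chromosome with gaps of at most 10 kb: 1386 regions, all autosomal, with 38090 probes and a median of 26 probes per region. The authors placed these probes around positions that had stood out in a first screen of the same family, so counts are not independent evidence of how often changes occur.

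An interval score was computed within each tiled region: the sum of log2 ratios over consecutive probes divided by the robust SD of the animal's profile and the square root of the probe number, taking the best interval first and then its flanks. An interval was called at a score of at least 6 in size, at least 3 probes, and a mean log2 ratio of at least 0.25 in size with the same sign on each of the 2 arrays. Noise was estimated by calling in a profile from which the animal's DNA cancels (the difference between the orientations, less its mean over animals per probe), without the rule on each array. Called intervals that shared a probe and a direction were merged into regions. An animal carried a region if its own interval covered at least 50% of the region's probes, or if its region mean passed 0.25 on both arrays with a score of at least 6. A region counted as found in offspring and neither parent only if both parents' means were under 50% of those of the carrying offspring. Parental regions were tested with an exact binomial test against 50%, two-sided. Tiled region means of the 8 animals were fitted with limma 3.58.1 in R 4.3.3, with the sire, the dam and the offspring as groups, two-sided, at a Benjamini-Hochberg adjusted p of 0.05; the sire and the dam are 1 animal each and are assumed to vary like the offspring. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

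The interval search was tested on simulated data over 38090 probes, with noise estimated from these arrays. Changes of -1.0 were recovered in 100% of cases at 3 probes, changes of -0.4 in 47.5% at 3 probes, 89.5% at 5 and 100% at 10 probes, and gains of 0.3 in 10.0% at 3 probes, 60.0% at 10 and 92.5% at 50 probes, with 0 false intervals. In simulated tables of 1386 tiled regions, limma recovered 97% of changes of 0.15 for offspring against parents, 95% for dam against sire and 100% for all animals against the reference, with 7, 10 and 3 false calls. The rates and false counts of both simulations hold for the simulated noise only. The noise profile of the real arrays, called without the rule on each array, did give intervals in the dam.

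Regions to be named were fixed before the data were examined: up to 25 merged regions with the largest mean in a carrying animal, up to 10 regions found in offspring and neither parent, up to 10 parental regions found in offspring, and 5 tiled regions per direction and limma fit with the largest difference past the threshold. Alternatives fixed at the same time were normexp with an offset of 50 on mean and background signals (run on median signals instead, since the files hold no mean signals of spots), the series value table, scores of 5 and 8, at least 5 probes, a mean of 0.4, no rule on each array, flagged probes kept, loess within arrays, a gap of 50 kb, 1 dye orientation only, each animal left out, slide as a block, slide 1 only, region medians, robust empirical Bayes and probes in place of regions. Removing running medians on probe brightness and probe length was added after the data were seen. The probes carry no gene names and the annotation at hand is of another build, so regions are given by mm9 coordinates, the planned overlap with gene families was not run, and neither was a correction for GC content, for which no genome of that build was used here.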

Results

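DNA copy number was compared within 1 family of C57BL/6 mice: a sire, a dam and their 6 offspring, each against the same reference male. The family is labelled with a gamma-ray dose of 0.05 mGy per day, and the series concerns transmission to progeny of males exposed for 400 days. The labels conflict on the sire, since the title names exposed males and 1 passage of the design text calls the male of this family non-irradiated, so no exposure status was assigned, and no family of another dose was analysed here. All 16 arrays, 2 per animal, were used. Ratios are log2 of animal over reference, and positions are on mouse build mm9.

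The sex chromosome probes separated the parents as their labels state. The mean over 48 X probes was 0.02 in the sire and 0.79 in the dam, and the mean over 3 Y probes was 0.05 in the sire and -1.49 in the dam. Offspring 1 and 2 had X means of 0.01 and -0.01 and Y means of -0.03 and 0.02. Offspring 3, 4, 5 and 6 had X means of 0.66, 0.67, 0.71 and 0.69 and Y means of -1.15, -1.13, -1.16 and -1.39. At 1 of the Y probes, none of the 10 spots was well above background in the DNA of the dam or of offspring 3 to 6, so their Y means are bounds on a larger difference. At the other 2 Y probes all 10 spots were well above background in these animals, with ratios of -0.92 to -0.55 and -0.26 to -0.15. Their Y means thus rest largely on the first probe, though all 3 were lower than in the sire and offspring 1 and 2. The 2 arrays of an animal correlated weakly over all autosomal probes, most of which lay near 0 in every animal: Pearson's r ran from -0.22 to 0.32 and Spearman's rho from -0.45 to -0.29. A dye effect of a probe has opposite signs on the 2 arrays so turned, and cancels in their mean. Over the 105 merged regions described below r was 0.34 to 0.91. These are correlations across probes or regions, which are not independent replicates, and the regions were called from the same arrays with a rule that both arrays pass.

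The number of copy number intervals differed widely between animals, along the division seen at the X and Y probes. The sire had 13 called intervals, the dam 60, and offspring 1 to 6 had 14, 6, 69, 76, 68 and 66. Of the 372 intervals, 304 were losses and 68 were gains. Losses made up 50 of the intervals of the dam and 57 to 71 of those of offspring 3 to 6, against 1 in the sire, 0 in offspring 1 and 4 in offspring 2. The dam and offspring 3 to 6 are the animals with high X and low Y means against the male reference. Sequence that differs between the sexes may therefore enter their counts, and offspring 3 to 6 also share slide 2. The median interval held 3 probes. The noise profile gave 2 intervals over the 8 animals, both in the dam, and 56 when the mean dye effect per probe was kept in it. There is 1 DNA per animal, so the counts carry no replicate error; requiring 5 probes lowered the total to 205 and requiring a mean of 0.4 lowered it to 193.

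**Figure D1:**
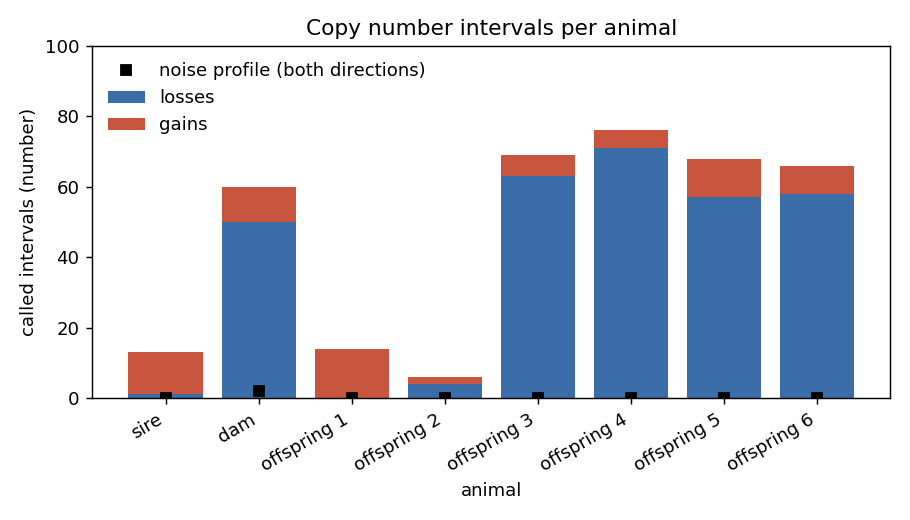
Called intervals (number) per animal, with losses and gains stacked and the number found in the noise profile as squares. The dam and offspring 3 to 6 had 60 to 76 intervals, and the sire and offspring 1 and 2 had 6 to 14. The same animals are set apart at the X and Y probes.

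The intervals merged into 105 regions on all 19 autosomes, 78 losses and 27 gains, of which 94 spanned 3 to 9 probes and 11 spanned 10 or more. The widest gain and the widest loss were seen on both arrays of every carrier. A gain over 161.9 kb at chr4:101109089-101270967 (1260 probes) had a mean of 0.59 in the sire, between 0.30 and 0.35 in each of the 6 offspring, and -0.02 in the dam. A loss over 30.6 kb at chr3:25416456-25447093 (85 probes) had a mean of -1.70 in the dam, -1.57, -1.57, -1.62 and -1.60 in offspring 3 to 6, and between -0.02 and -0.01 in the sire and offspring 1 and 2. On chromosome 14 between 53711639 and 54125512, 4 regions were lost together in the dam, offspring 2 and offspring 4. At chr14:53711639-53718002 (47 probes) these animals had -0.41, -0.40 and -0.37, at chr14:53756259-53761410 (26 probes) -0.40, -0.44 and -0.35, at chr14:53993275-53997454 (14 probes) -0.36, -0.30 and -0.29, and at chr14:54118526-54125512 (27 probes) -0.35, -0.32 and -0.29, while the other 5 animals lay between -0.05 and 0.03 in all of them. A gain at chr8:102191604-102201473 (25 probes) had 0.32 in the dam and 0.33, 0.34, 0.37 and 0.28 in offspring 3 to 6, against 0.00, 0.01 and 0.02 in the sire and offspring 1 and 2.

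**Figure D2:**
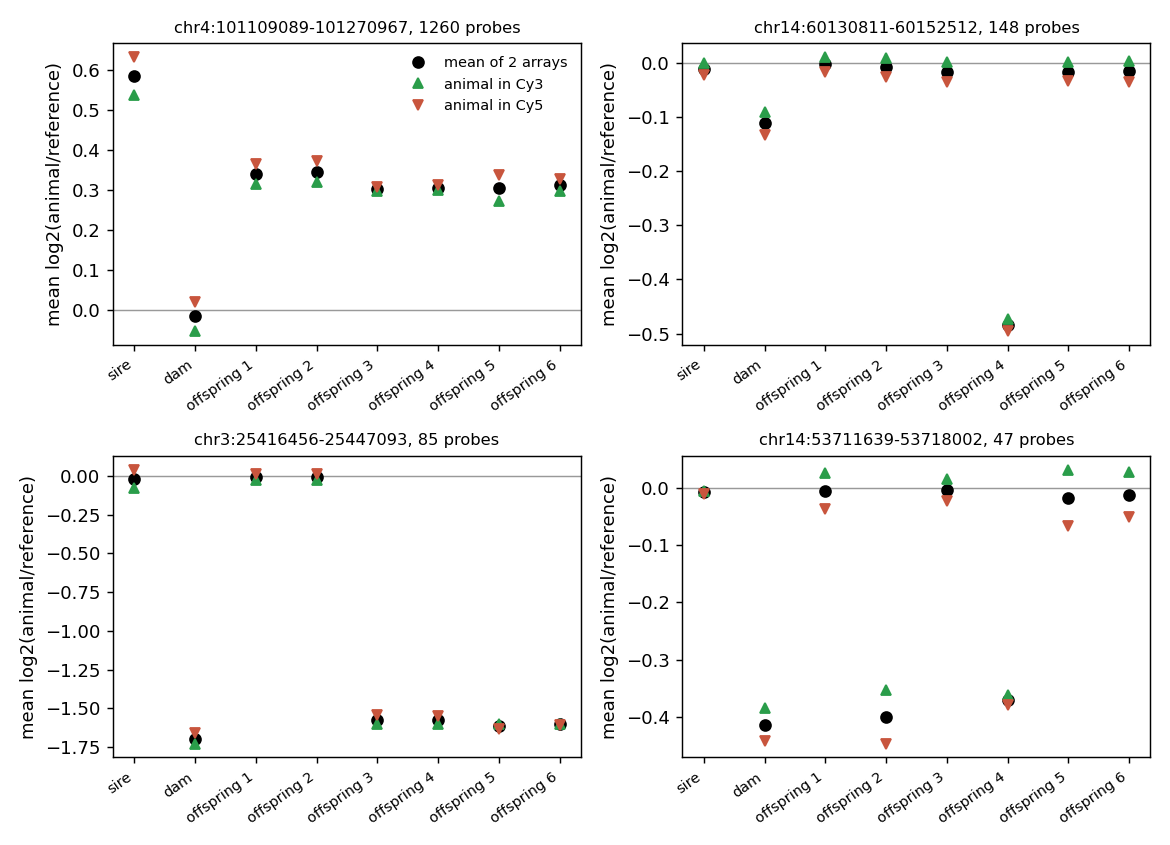
Mean log2(animal/reference) per animal over the 4 regions with the most probes, as the mean of both arrays (circles) and for each dye orientation (triangles). The sire has 0.59 on chromosome 4 with the offspring at 0.30 to 0.35, the dam and offspring 3 to 6 lie between -1.70 and -1.57 on chromosome 3, and offspring 4 has -0.48 at chr14:60130811-60152512.

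Of the 25 regions with the largest means, 21 were losses carried by the dam and offspring 3 to 6 and by no other animal. Beside the chromosome 3 loss, these were 20 short losses of 3 to 6 probes (0.096 to 1.80 kb), in which the carriers had means from -1.16 to -0.33 and the sire and offspring 1 and 2 had means from -0.11 to 0.13. The deepest were chr7:126944817-126944931, with -0.64 in the dam and -1.06, -1.09, -1.07 and -1.16 in offspring 3 to 6, chr7:18816858-18817395, with -0.89 in the dam and -1.08, -1.14, -0.94 and -1.09 in the same offspring, and chr3:132549431-132549728, with -1.01 in the dam and -0.93, -0.99, -1.06 and -1.06. Losses with a dam mean between -0.79 and -0.59 lay at chr13:77818414-77818665, chr6:138918425-138918768, chr10:78198893-78199209, chr9:13870826-13870990 and chr6:104241190-104241514. The remaining 12 began at 59716667 on chromosome 11, 56063695 and 27844872 on chromosome 1, 65230143 and 61802725 on chromosome 14, 167412903 on chromosome 2, 54976506 on chromosome 7, 40851245 on chromosome 16, 3892320 and 114585712 on chromosome 4, 108109529 on chromosome 5 and 39061697 on chromosome 10, with dam means from -0.52 to -0.36. The other 4 of the 25 were the chromosome 4 gain, a loss at chr14:60130811-60152512, a gain at chr13:113005727-113006080 in the sire, the dam and offspring 1 (0.45, 0.45 and 0.48), and a loss at chr6:132617532-132617845 in offspring 3 to 6 (-0.48, -0.40, -0.41 and -0.37). In the last of these the dam had -0.27 without passing the rules for a carrier, the score among them.

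**Figure D3:**
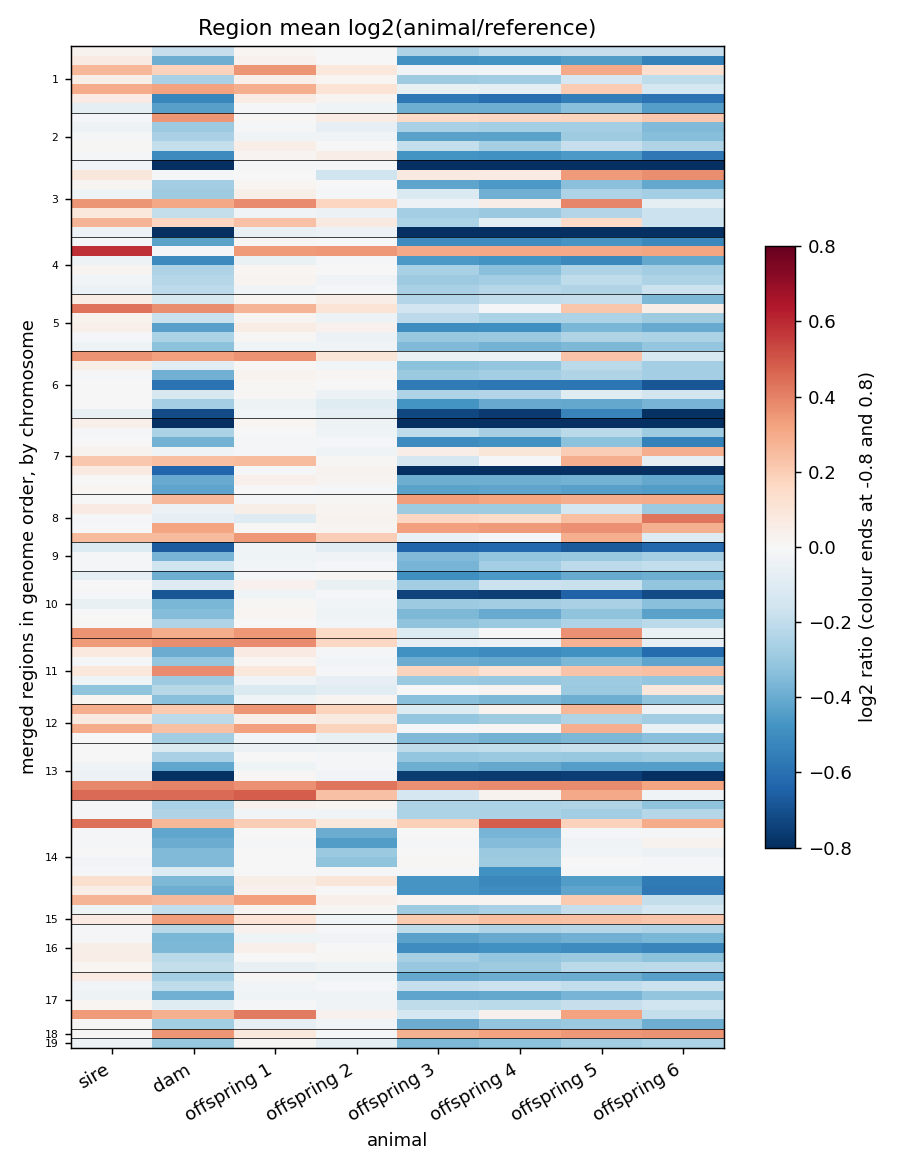
Mean log2(animal/reference) of the 105 merged regions (rows, in genome order) in each of the 8 animals (columns), with the colour scale ending at -0.8 and 0.8. The carrier set seen in most regions, 43 of 105, is the dam with offspring 3 to 6.

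Exactly 1 parent carried 64 regions, which asks how parental differences passed to the offspring. The dam alone carried 56 (51 losses and 5 gains) and the sire alone 8 (7 gains and 1 loss). Of the 56 regions of the dam, offspring 3, 4, 5 and 6 carried 48, 52, 48 and 46, offspring 2 carried 4, all of them on chromosome 14, and offspring 1 carried 0. In 43 of these regions 4 offspring were carriers. In 46 of the 51 losses of the dam, every offspring lay nearer the dam or nearer the sire as it did at the Y probes, and offspring 3 to 6 are also the offspring hybridised on slide 2, while both parents were on slide 1. Of the 8 regions of the sire, the chromosome 4 gain was carried by all 6 offspring; offspring 1 carried 6 and offspring 5 carried 3 of the 8, and the other 4 offspring carried 1 each. The dam had -0.02 at the chromosome 4 gain, but elsewhere carriage by the sire alone could depend on the thresholds. At chr12:108353481-108354390 the sire had 0.30 and the dam 0.23. After removing trends on probe brightness and length, the dam counted as a carrier there and the sire did not. After the same step the sire had 0.31 and the dam 0.23 at chr3:111012339-111012925, counted for the sire alone. Pooled, 211 of 384 combinations of region and offspring were carried, or 54.9% (95% exact interval 49.8% to 60.0%), a difference from 50% that missed the threshold (exact binomial test, two-sided, p = 0.0589). The regions are not independent of each other, so this p is too small. The share also followed the division of the offspring seen at the Y probes and between the slides. Most of the 64 regions, the 46 losses above, divided them so. The test therefore cannot decide how parental regions pass to offspring, and the share rests on how many offspring lie on each side. In the same binomial test it was 66.1% without offspring 1 (p = 1.4e-08) and 64.4% without offspring 2 (p = 3.0e-07), both past the threshold. Without any 1 of offspring 3 to 6 it lay between 49.4% and 51.6%, and missed the threshold each time. With the animal in Cy3 only the share was 36.8%, past the threshold in the other direction (p = 8.6e-05). In the same binomial test it passed above 50% after loess (p = 0.042) and at a score of 8 (p = 0.033). It also passed with a gap of 50 kb (p = 0.033) and after removing trends on probe brightness and length (p = 0.013).

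Of 34 regions carried by offspring and by neither parent, 27 were not counted as found in offspring alone, because a parent had at least 50% of the mean of a carrying offspring; 11 regions were carried by exactly offspring 3 to 6. The score divides by the robust SD of the profile, which was 0.10 in the dam and 0.05 to 0.07 in the offspring. A change of the same size thus scored lower in the dam, and her not being a carrier does not show its absence. The 7 counted were 4 losses and 3 gains. The one with the most probes was the loss at chr14:60130811-60152512, 21.7 kb and 148 probes, with a mean of -0.48 in offspring 4, -0.11 in the dam, and between -0.02 and 0.00 in the sire and the other offspring. The other 6 held 3 or 4 probes. Losses lay at chr9:117628233-117628455 in offspring 3 (-0.37), at chr6:76464206-76464894 in offspring 3 (-0.33) and at chr8:38352214-38352553 in offspring 3 and 4 (-0.29 and -0.29). Gains lay in offspring 6 at chr8:41671874-41672010 (0.43), chr3:29922204-29922435 (0.37) and chr7:95652733-95652858 (0.29); with normexp the means of the last 2 fell under 0.25, to 0.213 and 0.245. Which animals count as carriers in these 6 regions depended on the thresholds: offspring 6 had -0.29 at chr8:38352214-38352553, as low as the 2 carriers, but -0.14 on 1 array, and offspring 4 had -0.31 at chr6:76464206-76464894 and offspring 5 had 0.34 at chr3:29922204-29922435. In all 6, offspring 3 to 6 lay on the same side of 0. In 5, each of them lay further to that side than the sire and offspring 1 and 2. This is the division of the offspring seen at the Y probes and between the slides. The dam had -0.07 to -0.01 at the gains and -0.16 to -0.05 at the short losses. The rule for these regions required low parental means, so her values cannot tell the 2 divisions apart. The count was 5 with normexp, 4 without offspring 6, 3 with a mean of at least 0.4, and 18 with flagged probes kept.

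A gain at chr13:95705972-95707908 (4 probes) was the 1 region carried by all 8 animals, with means of 0.38 in the sire, 0.39 in the dam and 0.31 to 0.43 in the offspring. A difference of the reference mouse gives the same result as a gain in the whole family. It was 0 regions where at least 5 probes were required.

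Offspring and parents differed little over whole tiled regions. The mean of the 6 offspring was higher than the mean of the sire and the dam in 43 of 1386 tiled regions and lower in 20 (limma, adjusted p from 0.0331 to 0.0494), with a median difference of 0.05 and a largest of 0.09 in size. The largest higher differences were 0.08 at chr18:51162713-51164399, chr2:24477550-24479345 and chr6:134373253-134375802 and 0.06 at chr2:25282183-25285454 and chr17:34978306-34980869, and the largest lower ones were -0.09 at chr2:41512743-41519509 and chr5:19399018-19402290, -0.07 at chr9:123934728-123938387 and chr3:150006967-150009734 and -0.06 at chr16:79698867-79709625. At chr2:41512743-41519509 the sire had 0.06, the dam 0.10 and the offspring -0.01 ± 0.03 (SD, n = 6). The 63 calls fell to 0 without any 1 of offspring 1, 2, 3 and 4 and to 1 without the dam; they were 26 with slide as a block, 171 on slide 1 alone, which holds both parents, and 0 after loess, after normexp and after removing trends on probe brightness and length. Slide 2 held only offspring, so the slide term rested on offspring 1 and 2 against offspring 3 to 6. That is the same division as at the sex chromosome probes, and the fit cannot tell the 2 apart. On slide 1 alone the spread came from offspring 1 and 2. The profile of the dam was the noisiest, with a robust SD of 0.10 against 0.05 to 0.07 in the other animals. She may therefore not vary like the offspring, as the fit assumes. The adjusted p may then be too small, here and for the dam against the sire.

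Between the dam and the sire, 1 tiled region of 1386 passed the threshold and 0 were higher in the dam. It was the region at chr4:101107910-101271534 (1271 probes), with -0.02 in the dam, 0.58 in the sire and 0.32 ± 0.02 (SD, n = 6) in the offspring, a difference of -0.60 ± 0.02 (SE; limma, adjusted p = 2.6e-06). Each parent is 1 animal and the spread came from the offspring, which differ among themselves at the chromosome 3 and 14 losses. With slide as a block 11 regions passed, on slide 1 alone 57, and 958 single probes passed when probes replaced regions.

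Over the 8 animals together, 23 tiled regions were higher and 144 lower than the reference (limma, adjusted p from 0.0032 to 0.0496), of which 165 differed by under 0.25. The largest higher means were 0.31 ± 0.16 (SD, n = 8) at chr4:101107910-101271534, 0.20 ± 0.16 at chr8:102191491-102201473, 0.08 ± 0.06 at chr14:52006314-52021332, 0.06 ± 0.05 at chr3:133585538-133588231 and 0.06 ± 0.06 at chr12:108352333-108355117. The largest lower means were -0.91 ± 0.74 at chr3:25415551-25447093, -0.13 ± 0.11 at chr14:61802521-61806125, -0.13 ± 0.10 at chr13:77815699-77818665, -0.10 ± 0.07 at chr7:18815575-18820415 and -0.10 ± 0.08 at chr7:126942829-126946037. The animals fall into carriers and non-carriers at the called regions among these, and the test leaves out the spread of the reference. The 167 calls became 85 without the sire, 97 without offspring 1, 95 without offspring 3 and 58 without offspring 5; they were 261 with slide as a block and 18 on slide 1 alone.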

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

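Tests chosen only after the result was seen are those of the share of the dam's cells and of mixed DNA; the test of the probe trend was written beforehand. At chr14:60130811-60152512 the mean of offspring 4, -0.48, lay far from the other 5 offspring, which had -0.02 to 0.00. The gap was 0.971 of the range of the 6 values. It was the 1 case flagged among 57 sets of 6 values examined. Chance flags about 1 set in 20, so 1 flag among 57 is no more than chance gives. The region was also called from the same values of offspring 4, so the flag adds no separate evidence. Both dye orientations showed the low mean of offspring 4. A trend of the log2 ratio on probe brightness and length is argued against, since the mean was -0.48 before and -0.484 after that trend was removed. The dam had -0.12 there after the same step, lower than in all but 0.157% of her 1275 tiled regions without calls and with at least 20 probes, and no other animal but offspring 4 was as low among its own regions; a minimum of 50 probes, chosen first, left only 12 regions. A candidate explanation is therefore a loss in part of the dam's cells, germ line included, that passed to offspring 4, while DNA of offspring 4 in the dam's sample is argued against: it would put the dam at 0.09 in the chromosome 4 gain, where she had -0.0088 (SD of her tiled regions 0.03). A change that arose in offspring 4 itself, with a wave of unknown origin in the dam, stays open, and the exposure of the sire was not tested because the labels conflict and no other family was analysed here.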

How the results depend on the processing

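The trend removal, and median in place of mean signals in normexp, were chosen after seeing the data; the other alternatives were fixed before. With the main values first, the 372 intervals, 105 merged regions, 7 regions of offspring only, 64 parental regions and 1 region shared by all animals became 205, 64, 4, 37 and 0 with at least 5 probes and 193, 57, 3 and 37 with a mean of at least 0.4. Regions of offspring only were 18 with flagged probes kept, 26 with no rule on each array, 15 with the animal in Cy3 only and 11 with the animal in Cy5 only; with the animal in Cy3 only, parental regions were 38 and shared regions 0. Leaving out each offspring gave 4 to 7 regions of offspring only, 4 without offspring 6. The share of offspring carrying a parental region, 54.9%, passed the threshold above 50% after loess (55.1%), at a score of 8 (56.7%), with a gap of 50 kb (55.6%), after trend removal (56.4%), and without offspring 1 (66.1%) or 2 (64.4%), passed it below 50% in Cy3 only (36.8%, p = 8.6e-05), was 49.7% in Cy5 only, and ran from 49.4% to 66.1% without 1 offspring.

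Calls for offspring against parents (63) were 0 with normexp, loess, the animal in Cy5 only or trend removal, 15 with flagged probes kept, 155 with region medians, 1 with probes, 306 with the animal in Cy3 only, 26 with slide as a block and 171 on slide 1 only, and ran from 0 to 78 without 1 animal. At an unadjusted p of 0.05, 384 tiled regions passed with normexp, 275 with loess, 215 after trend removal and 27 in Cy5 only. The named tiled region at chr18:51162713 turned from 0.08 to -0.01 in Cy5 only. Calls for dam against sire (1) were 2 with flagged probes kept, 2 with region medians, 958 with probes, 11 with slide as a block and 57 on slide 1 only. Calls for all animals against the reference (167) were 43 with region medians, 1931 with probes, 908 in Cy3 only, 887 in Cy5 only, 261 with slide as a block, 18 on slide 1 only and 58 to 239 without 1 animal. Probes in place of regions changes the number of tests, and 1 orientation keeps the dye effect; for the others the cause was not tested. The median dye-swap correlation moved from 0.13 to -0.08 with normexp. Of 160 values of named called regions under other signals, 158 kept their side of 0.25 and 2 fell below it. These were the gains of offspring 6 at chr3:29922204 and chr7:95652733 with normexp (0.213 and 0.245). Only the carrier with the largest mean was followed in each region. The series value table, 1 of these signals, nearly repeats the main values and could not change the count. Of 190 values of tiled regions named for offspring against parents, 104 lost their call. Leaving out saturated probes was not run, since none was saturated, and neither were the GC correction and the gene family alternatives. Signal over background is the limit of dim probes, with 622 to 2083 spots per array left out for it.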

Other observations

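The tests in this part were chosen after the result was seen, except that of the probe trend for gains carried by both parents. The chromosome 14 losses between 53711639 and 54125512 were not distributed among the offspring like the other losses of the dam. Offspring 2 and 4 carried all of the 4 regions, and offspring 1, 3, 5 and 6 carried none. Of the short gains of the dam, 2 had no carrier among the offspring, chr2:70084763-70085196 (0.35 in the dam and 0.15 to 0.22 in offspring 3 to 6) and chr11:81803928-81804323 (0.38 in the dam and 0.12 to 0.24 in the same offspring). A gain at chr14:52008939-52021220 had 0.44 in the sire and 0.26 in the dam, its 2 carriers. Offspring 4 had 0.48 and the other offspring 0.08 to 0.29, but none passed the rule on each array, and the values there differed by dye: offspring 4 had 0.18 in Cy3 and 0.79 in Cy5, and offspring 3 had -0.11 and 0.50.

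At the chromosome 4 gain the excess of the offspring over the reference, as a linear ratio minus 1, was 0.494 ± 0.03 (SD, n = 6) of the excess of the sire, with a range of 0.465 to 0.543. This is consistent with extra copies on both chromosomes 4 of the sire, each offspring receiving 1 of them. A sire with the gain on 1 chromosome passes it to all 6 offspring with a chance of 0.0156.

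Of the 51 losses carried by the dam and not the sire, 46 on 15 chromosomes had every one of the 6 offspring nearer the dam or nearer the sire just as at the Y probes. Independent inheritance of autosomal losses predicts 0.797 such regions, with an upper 95% limit of 3, so it is argued against for these 46. The chromosome 3 loss, 1 of the 46, had -1.62 to -1.57 in offspring 3 to 6 and -0.02 in the sire. If the sire and the reference hold 2 copies each, losing only the copy from the dam gives a log2 ratio of -1.0. The lower values argue against that loss alone for this region. A difference between slides is argued against as the whole cause too: of the 72 losses carried by offspring of slide 2 and by none of slide 1, the dam, on slide 1, carried 46 and the sire 0. Sequence shared between these autosomal probes and the Y chromosome may account for the 46, in which case they would follow the sex of the animal. X probes were higher in the dam and offspring 3 to 6 (means of 0.66 to 0.79), so sequence shared with X would give gains there. No genome was searched, and other differences between the sexes stay open and untested. Of the 5 remaining losses, 4 are those on chromosome 14.

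Gains carried by both parents but not by all animals numbered 6; 5 lay on dim probes, at percentiles of 7.45 to 17.3 of probe brightness, and the gain at chr14:52008939-52021220 lay at 93.3. Over all 6, the median correlation of the offspring means was 0.93 (15 pairs on different chromosomes) against an upper 95% limit of 0.326 in 1000 shuffles; for the 5 dim gains, set apart after the correlations had been seen, it was 0.945 (0.835 to 0.985 over 10 pairs) against a limit of 0.49 when each shuffle kept the 5 of 6 that correlated most, and it stayed above its limit (0.551 to 0.654) with each offspring left out in turn, which argues against independent inheritance of these 5, while the chromosome 14 gain had -0.518 to -0.312 with them and stays open. Removing the trend on probe brightness and length left 1 of the 6 carried by both parents, that at chr13:113005727-113006080. In the 5 others the call ended with the mean of the dam under 0.25 on 1 array (0.15 to 0.20). At chr11:58085320-58085473 the sire was under 0.25 on 1 array too (0.19). Over the 6 regions the mean went from 0.35 ± 0.07 to 0.29 ± 0.04 (SD) in the dam and from 0.40 ± 0.05 to 0.37 ± 0.06 in the sire, and 17 of 19 means of carriers over both arrays (89.5%) were at or above 0.25 after the removal, so the trend is argued against as the whole size of the gains, though the calls in both parents depended on it. A difference between slides stays open, since the median range among the 4 offspring of slide 2 was 0.367 against a median difference of 0.215 between slides, but 0.139 against 0.306 without offspring 5; for the 5 dim gains a property of each DNA sample that acts on a subset of probes may remain too, which was not tested, nor was any biological explanation beyond inheritance.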
